A study of Mus musculus with 2 samples.

How the data were processed

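The data came from 1 cDNA library and 1 hashtag library, both made from the same pooled cells of collagen and Matrigel cultures on day 4. Per the labels, cells were captured on the BD Rhapsody system and both libraries were amplified by TAS-Seq, a method for cDNA on beads, and sequenced on an Illumina instrument. Per the submitters' processing notes, cutadapt 4.1, STARsolo 2.7.10a and R 4.2.1 were used with the GRCm39 mouse genome build. The notes list these names with no role or order, and the gene annotation is not given in the sources used here. No coordinates are given, because the annotation at hand was of another build, and genes are named by the symbols in the deposited table.

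The expression table deposited by the authors holds expected counts per gene and cell for 37172 genes and 2090 cells, not scaled. Of the values above 0, 75.6% were whole numbers (within 1e-06) and the rest were fractional. Whether reads of the same molecule were collapsed is not given in the sources used here, so the values are called counts and not molecules. Intervals for sums treat each count as independent and are too narrow if copies of a molecule were counted. Sums were rounded to whole numbers before intervals were computed. The design fixed beforehand spoke of molecules counted by identifiers, and the same calculations were applied to these counts. The first 49 genes of the table lacked low values. Their smallest values above 0 ran from 3.33 to 183, while 99.8% of the other genes had one of at most 1, as after a background threshold set per gene. The hashtag table deposited by the authors holds whole-number counts of 11 hashtag sequences for 200497 barcodes, including all 2090 cells.

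Cell names in the deposited expression table carry the hashtag of a culture or the word doublet, and these names set the condition, with A952 for collagen and A953 for Matrigel per the labels. They gave 336 collagen cells, 1615 Matrigel cells and 139 cells named as doublets, which were left out of the comparisons except in the alternatives that set the culture by hashtag share. A share of 60% put 49 of these among the collagen and 54 among the Matrigel cells, and a share of 95% put 5 among the collagen cells. The median share of the own hashtag among both was 99.4% in collagen cells, and 3 collagen and 7 Matrigel cells lay below 80%. Cells with at least 500 detected genes and at most 30% mitochondrial counts were kept, which removed 16 Matrigel cells and 0 collagen cells. Scrublet, run in scanpy 1.11.5, called 1 of 1935 cells a doublet, so it found almost none and served only as an alternative.

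Counts were summed over the cells of a condition and scaled to a total of 1000000 per condition (CPM). The log2 ratio was log2((collagen CPM + 1)/(Matrigel CPM + 1)), which understates the ratio of genes with low levels. No test across samples was possible with 1 suspension per culture, and no p-value was computed. Exact Poisson and Clopper-Pearson binomial intervals at 95% were computed with scipy 1.17.1.

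The 38 gene lists, the class markers and the rule for naming genes were chosen before the data were examined. Genes reaching 50 CPM in the higher condition with at least 100 counts were eligible (2944 genes), without mitochondrial, ribosomal, predicted, clone and pseudogene names. The 12 with the largest log2 ratio in each direction were named, with up to 4 members of each list (reaching 10 CPM, largest absolute log2 ratio first) and with Lgr5, Olfm4, Lyz1, Muc2, Chga, Dclk1, Alpi, Fabp1, Mki67, Ly6a, Anxa1, Clu, Ccn1, Ccn2, Axin2 and Epcam in every case. Some genes that the rule names are not reported here. Zinc transporter genes in the closing part were chosen after the values of the metallothionein genes were seen. Across the lists, 7 symbols had no entry and are not analysed here.

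List members entered when they reached 5 CPM in either condition. Each list's median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of expression, as a description of these cells. Lists with fewer than 3 members measured (tuft, fibroblast, immune, endothelial, and muscle, mesothelial and neural) got no percentile. On counts simulated for collagen against Matrigel at the real depths over 37172 genes, 98.9% of 95 genes changed 2-fold and 100% of 105 genes changed 4-fold came within 0.1 of the simulated log2 ratio. The simulation drew Poisson sums, with changes only in genes of at least 50 CPM and no differences between cells. It therefore checks the calculation and not the reliability of the ratios. Of 400 random lists of 12 genes, drawn from 10593 genes, 4.5% fell outside their own 95% range, and 100% of 50 lists shifted by 1 on the log2 scale lay above it.

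For shares of cells with a marker, each cell was thinned without replacement to 77972 counts, the percentile 10 of counts per kept cell, and shallower cells were left out. For clusters, counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes without mitochondrial and ribosomal protein genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 1, seed 0) were used. Clusters could be named enterocyte-like, goblet or Paneth-like, enteroendocrine-like or regenerative. A name needed at least 3 of the class's fixed markers among the 10 leading genes, and no other marker set with as many. Markers of other cell types, those of stem cells and of dividing cells included, could name no cluster. A cluster of 65 Matrigel and 2 collagen cells had 3 stem cell markers among its leading genes and stayed unnamed. Goblet and Paneth markers led the same clusters and were joined. A regenerative name, fixed like the others, covered from 47.3% to 93.6% of collagen cells across the settings and was not used. A comparison within a class needed 50 cells in both conditions, which no class had.

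Alternatives fixed beforehand covered scaling, weighting of cells, pseudocount, cell filters, hashtag share, thinning, doublet calls, filters on list members and clustering settings. Zeros of the 49 genes set to the smallest kept value, and all results without the cluster of highest mitochondrial share, were chosen after seeing the data. A list median that moved by under 0.25 log2, a gene ratio that moved by under 0.6 log2 and a share inside its main interval were counted as unchanged, and these bounds were set with the data at hand but before the alternatives were computed.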

Results

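Cells from mouse small intestinal organoids grown in Matrigel were compared with cells from organoids grown in type I collagen. Organoids are clusters of epithelium grown from isolated crypts, and both cultures came from crypts of C57BL/6 wild-type mice. Matrigel, a basement membrane extract, was overlaid with medium holding EGF, Noggin and R-spondin1, and gave budding organoids. Collagen cultures received the same medium with Wnt3a at 100 ng/mL, nicotinamide at 10 mM and 1% bovine serum albumin, and gave cystic spheres. Cells were harvested on day 4, tagged by culture with a hashtag (a barcoded reagent bound through an EpCAM antibody) and sequenced as 1 pooled single-cell library. There were 336 collagen cells and 1615 Matrigel cells, and a filter on mitochondrial share left 336 and 1599. The kept collagen cells held 42540314 counts (median 124619 per cell, range 30139 to 708341; median 7893.5 detected genes). The kept Matrigel cells held 285201649 counts (median 179044 per cell, range 30219 to 533149; median 9459 detected genes). The median mitochondrial share was 3.43% in collagen cells and 4.63% in Matrigel cells.

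Each culture was a single cell suspension, so no difference has a replicate check and no test was run. Matrix, medium and the way cells were released (collagenase at 0.5 mg/mL for collagen, a non-enzymatic recovery solution for Matrigel) differed together. Levels are summed counts scaled to a total of 1000000 (CPM), given for collagen first and Matrigel second, and log2 ratios are collagen over Matrigel with 1 CPM added. Intervals are exact 95% Poisson intervals for sums and exact 95% binomial intervals for shares. Neither kind covers the spread between repeated cultures. Poisson intervals treat each count as independent and leave out the spread between cells. They are too narrow if the counts include copies made by PCR.

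The first question was which genes differed between cells from the collagen and the Matrigel cultures. Collagen cells had far higher levels of genes known from fetal and injured intestinal epithelium, and far lower levels of crypt stem cell genes and of some Wnt targets. Msln, which encodes the surface protein mesothelin, stood at 184 CPM (180 to 188) against 0.845 CPM (0.742 to 0.959). Ly6a, the gene of the stem cell antigen Sca-1, stood at 232 CPM (227 to 236) against 4.47 CPM (4.23 to 4.73). In the other direction Olfm4, a crypt stem cell marker, stood at 31.2 CPM (29.6 to 32.9) against 1637 CPM (1632 to 1642). Axin2, a feedback gene of canonical Wnt signalling, stood at 15.2 CPM (14.1 to 16.5) against 163 CPM (162 to 165), although Wnt3a was added to the collagen medium alone.

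The 12 genes with the largest ratio toward collagen were led by Msln (log2 ratio 6.65) and Sprr1a, a cornified envelope gene (5.84; 155 against 1.72 CPM). Sprr1a had a count in 74 of 336 collagen cells and was a leading gene of a cluster of 26 shallow collagen cells and 1 Matrigel cell, at 2037 CPM against 12.8 CPM in all other cells, and the log2 ratio of Sprr1a was 6.06 after thinning. Ly6a followed at 5.41, Lgals3, which encodes galectin-3, at 5.09 (714 against 20.1 CPM), and S100a6, which encodes a calcium-binding protein, at 5.06. S100a6 was also abundant, at 5705 CPM (5682 to 5727) against 169 CPM (168 to 171). The mucin gene Muc3 had a log2 ratio of 4.99, the glutathione transferase gene Gsta1 4.96, the interleukin-1 receptor antagonist gene Il1rn 4.59 and Tm4sf4 4.59. Muc3, Il1rn, Tm4sf4 and Lgals3 were leading genes of a cluster of 120 collagen and 2 Matrigel cells. Muc3 stood at 273 CPM there and Il1rn at 105 CPM, against 8.82 and 3.20 CPM in all other cells. Wfdc2, S100a6, Msln, Ly6a and Clu were among the leading genes of another cluster, of 159 collagen cells. Clu, which encodes clusterin and marks regenerating intestinal epithelium, had a ratio of 4.49 (365 against 15.3 CPM), Wfdc2 4.38 and Anxa1, which encodes annexin A1, 4.38 (119 against 4.76 CPM). For Gsta1, 99.7% of the values above 0 were not whole numbers, as arises when reads are shared between near-identical genes, so its level is uncertain. Such values made up 81.4% for Olfm4 and 73.5% for Defa30, named below, so their levels carry the same uncertainty.

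The 12 genes with the largest ratio toward Matrigel included Defa30, an alpha-defensin gene of Paneth cells, which was listed at 0 in all collagen cells and at 54.9 CPM in Matrigel cells, where 34 cells carried it. Olfm4 had a log2 ratio of -5.67 and the metallothionein gene Mt2 one of -5.51 (74.3 against 3424 CPM). Its neighbour in function, Mt1, had a ratio of -3.54 (393 CPM, 387 to 399, against 4572 CPM, 4564 to 4580). The water channel gene Aqp4 had a ratio of -5.27 (2.59 against 137 CPM), Gkn3 -4.41 (1.95 against 61.6 CPM) and Rgcc -3.85. Ccn1, a secreted matricellular gene, had a ratio of -3.70 (17.0 against 234 CPM), Ifitm3 -3.58 and Axin2 -3.34. Cps1, the urea cycle's carbamoyl phosphate synthetase, had a ratio of -3.23 (69.4 against 660 CPM) and Sdsl -3.20. Ly6a, Lgals3, S100a6, Gsta1, Tm4sf4, Clu, Defa30, Olfm4 and Mt2 are among 49 genes whose low values are absent from the deposited table. With every 0 of these genes set to the smallest value kept, the log2 ratio was 2.77 for Ly6a, 2.59 for Clu, 3.89 for Lgals3, 3.56 for Gsta1, 3.14 for Tm4sf4, -3.71 for Olfm4, -2.68 for Mt2 and -0.06 for Defa30, so no difference in Defa30 is shown. Except for Defa30, the ratios toward Matrigel named here also shrank when a hashtag share of 60% set the culture, which placed 49 cells named as doublets among the collagen cells and 54 among the Matrigel cells. They were then -3.03 for Olfm4, -3.60 for Mt2, -2.82 for Mt1, -3.21 for Aqp4, -2.66 for Gkn3, -2.93 for Rgcc, -2.86 for Ccn1, -2.64 for Ifitm3, -2.65 for Axin2, -2.54 for Cps1 and -2.46 for Sdsl. At 95%, with 5 cells named as doublets among the collagen cells, Olfm4 was at -8.38, Mt2 at -6.70, Aqp4 at -5.92 and Gkn3 at -5.07. The collagen level of Olfm4 rested on 3 cells and that of Mt2 on 9.

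**Figure D1:**
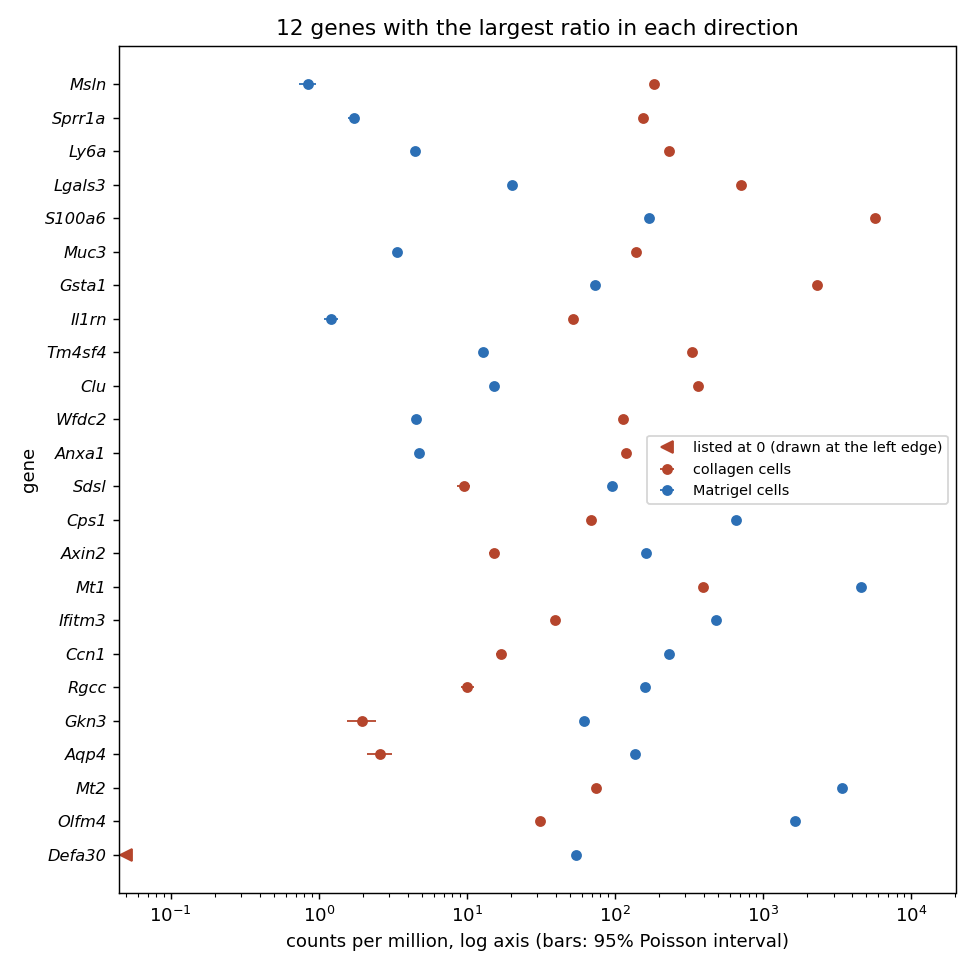
CPM (log axis) in collagen and Matrigel cells for the 12 genes with the largest log2 ratio in each direction, with exact 95% Poisson intervals as bars. Msln stands at 184 against 0.845 CPM and Olfm4 at 31.2 against 1637 CPM, and Defa30 is listed at 0 in collagen cells.

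The second question was which groups of genes moved together, taken from 38 fixed lists. In the fetal and regenerative epithelium list, 13 of 14 measured members were at least 2-fold higher in collagen cells and the median log2 ratio was 4.17. All 10000 random lists matched on expression had lower medians, with 95% of them between -0.37 and 0.38. With every member that had a count, the median of this list was 2.25. In the stem cell list, 9 of 11 measured members were at least 2-fold lower and 1, Prom1, was at least 2-fold higher (184 against 89.0 CPM); the median was -2.32, below all random lists. Gkn3, Ascl2 (2.44 against 43.7 CPM; log2 ratio -3.70, or -2.86 at a hashtag share of 60%), Olfm4 and Axin2 were the furthest toward Matrigel, and Lgr5, the receptor gene that marks cycling crypt stem cells, stood at 33.0 CPM (31.3 to 34.8) against 134 CPM (132 to 135). The Wnt target list had 8 of 14 members at least 2-fold lower and none at least 2-fold higher, with 6 within 2-fold and a median of -1.12. Its measured members Ascl2, Axin2, Lgr5 and Rnf43 (43.9 against 56.2 CPM) are shared with the stem cell list, and Sp5 stood at 1.97 against 15.6 CPM. Of the 33 lists with at least 3 measured members, 13 had a median above and 8 a median below the range of 95% of their random lists. With lists of genes drawn independently, 1.65 would lie outside. The fixed lists share members and their genes may vary together, so that number is not a chance expectation for them. The median log2 ratio over all 10593 genes reaching 5 CPM was -0.02.

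Proliferation genes divided by phase. In the S phase list, 22 of 25 measured members were at least 2-fold lower in collagen cells and none was at least 2-fold higher, with a median log2 ratio of -1.62, below all random lists. The DNA repair gene Ung stood at 8.93 against 65.1 CPM, Uhrf1 at 9.57 against 65.6 CPM, Dtl at 6.35 against 38.0 CPM and the replication helicase gene Mcm5 at 27.9 against 151 CPM. In the G2/M list, 22 of 25 members lay within 2-fold and the median was 0.13, at percentile 81.8 of its random lists. Its exceptions were Hmmr (33.8 against 11.9 CPM), Cenpf (45.4 against 16.5 CPM) and Cenpe (42.6 against 20.6 CPM), all higher in collagen. Mki67 stood at 65.5 CPM (63.1 to 68.0) against 45.7 CPM (45.0 to 46.5), while Cdk1 was lower in collagen at 26.2 against 46.3 CPM.

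The keratin, basement membrane and adhesion lists had medians above 0, toward collagen cells. The keratin and squamous-type list had 11 of 12 members at least 2-fold higher, with a median of 1.91, or 1.14 with every member that had a count. Ly6d stood at 18.5 against 0.0631 CPM, with a count in 23 of 336 collagen cells. It led the cluster of 26 shallow collagen cells (median 45060 counts per cell), in which Sprr1a, Msln, Lgals3, Tpm2 and Anxa10 were also leading genes, at 482 CPM there against 0.352 CPM in all other cells, and the log2 ratio of Ly6d, 4.19, was 1.58 after thinning, which leaves out shallow cells. Krt20, a keratin of differentiated intestinal cells, stood at 107 against 8.03 CPM, and Sprr2a3, which shares reads with near-identical copies, at 716 against 116 CPM. Of 8 basement membrane genes, 5 were at least 2-fold higher and 1 at least 2-fold lower (median 1.97, or 1.04 with every member that had a count), with the laminin gene Lama5 at 39.2 against 6.65 CPM and Agrn at 119 against 31.4 CPM. The integrin, focal adhesion and actin list had 12 of 29 members at least 2-fold higher, 16 within 2-fold and 1, Cnn3, at least 2-fold lower (47.9 against 139 CPM), with a median of 0.76. Its largest ratios were those of the tropomyosin gene Tpm2 (14.8 against 0.157 CPM), the calponin gene Cnn2 (110 against 11.1 CPM) and Anxa2 (1155 against 185 CPM). The 3 medians stood above all of their random lists.

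The targets of the mechanosensitive co-activators YAP and TAZ did not all go one way. Of 17 measured members, 7 were at least 2-fold higher in collagen cells and 2 at least 2-fold lower, and the median of 0.66 was at percentile 99.96. Myof (58.0 against 5.02 CPM), F3, which encodes tissue factor (62.5 against 6.21 CPM), and Ccn2 (17.9 CPM, 16.6 to 19.2, against 4.87 CPM, 4.61 to 5.13) were higher. Ccn1 and the endothelin gene Edn1 (31.9 against 188 CPM) were lower. With members limited to those reaching 20 CPM, the median was 0.27. In the BMP and TGF-beta list the median was 0.89 over 7 members, with Id2 at 193 against 73.5 CPM and Bmp7 at 1.53 against 20.2 CPM, a log2 ratio of -3.07 that was -2.40 at a hashtag share of 60%. With every member that had a count, the median of this list was -0.030.

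The lists of glycolysis, fatty acid oxidation, sterol synthesis and p53 target genes had medians above 0, toward collagen cells. Glycolysis and hypoxia genes had a median of 0.72, with 8 of 21 at least 2-fold higher and none at least 2-fold lower. Hexokinase Hk1 stood at 53.3 against 11.7 CPM, Adm at 25.2 against 5.25 CPM, Egln3 at 148 against 40.0 CPM and the glucose transporter gene Slc2a1 at 124 against 41.1 CPM. Fatty acid oxidation genes had a median of 0.57 (4 of 15 at least 2-fold higher), with Cpt1a at 109 against 50.9 CPM. Sterol synthesis genes had a median of 0.65, with 15 of 18 within 2-fold. Their examples were Sc5d (138 against 62.1 CPM) and Mvd (162 against 78.7 CPM), while Insig1 was lower at 51.9 against 114 CPM. The p53 target list had 7 of 14 members at least 2-fold higher (median 0.91), with the cell cycle inhibitor gene Cdkn1a at 314 against 78.3 CPM, Ccng1 at 163 against 39.9 CPM, Trp53inp1 at 21.7 against 3.11 CPM and Phlda3 at 34.1 against 8.34 CPM. The bile acid, drug and retinoid metabolism list was split, with 5 of 15 members at least 2-fold higher and 6 at least 2-fold lower, and its median of 0.44 was -0.064 with every member that had a count. Its members Gsta4 (1968 against 127 CPM) and Fgf15 (10.6 against 0.132 CPM) were higher and Rbp2 (10.6 against 49.3 CPM) was lower. Rbp2 was a leading gene of a cluster of 56 Matrigel cells, at 891 CPM there against 15.9 CPM in all other cells.

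Genes often read as signs of RNA quality and handling also differed. Whether handling or the culture changed them was not tested. The mitochondrially encoded list had a median of -0.41, with all 13 members within 2-fold. Its member mt-Nd4 stood at 2758 against 4660 CPM, though 99.9% of its values above 0 were not whole numbers. The nuclear RNA Malat1 stood at 986 against 370 CPM and Neat1 at 92.7 against 23.8 CPM. In the immediate-early and heat shock list, 6 of 18 members were at least 2-fold lower in collagen cells and 2 at least 2-fold higher (median -0.47). Fosb (3.77 against 21.1 CPM) and Atf3 (19.7 against 90.2 CPM) were lower, and the heat shock genes Hspa1a (10.7 against 0.903 CPM) and Hspa1b (22.0 against 2.27 CPM) were higher.

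**Figure D2:**
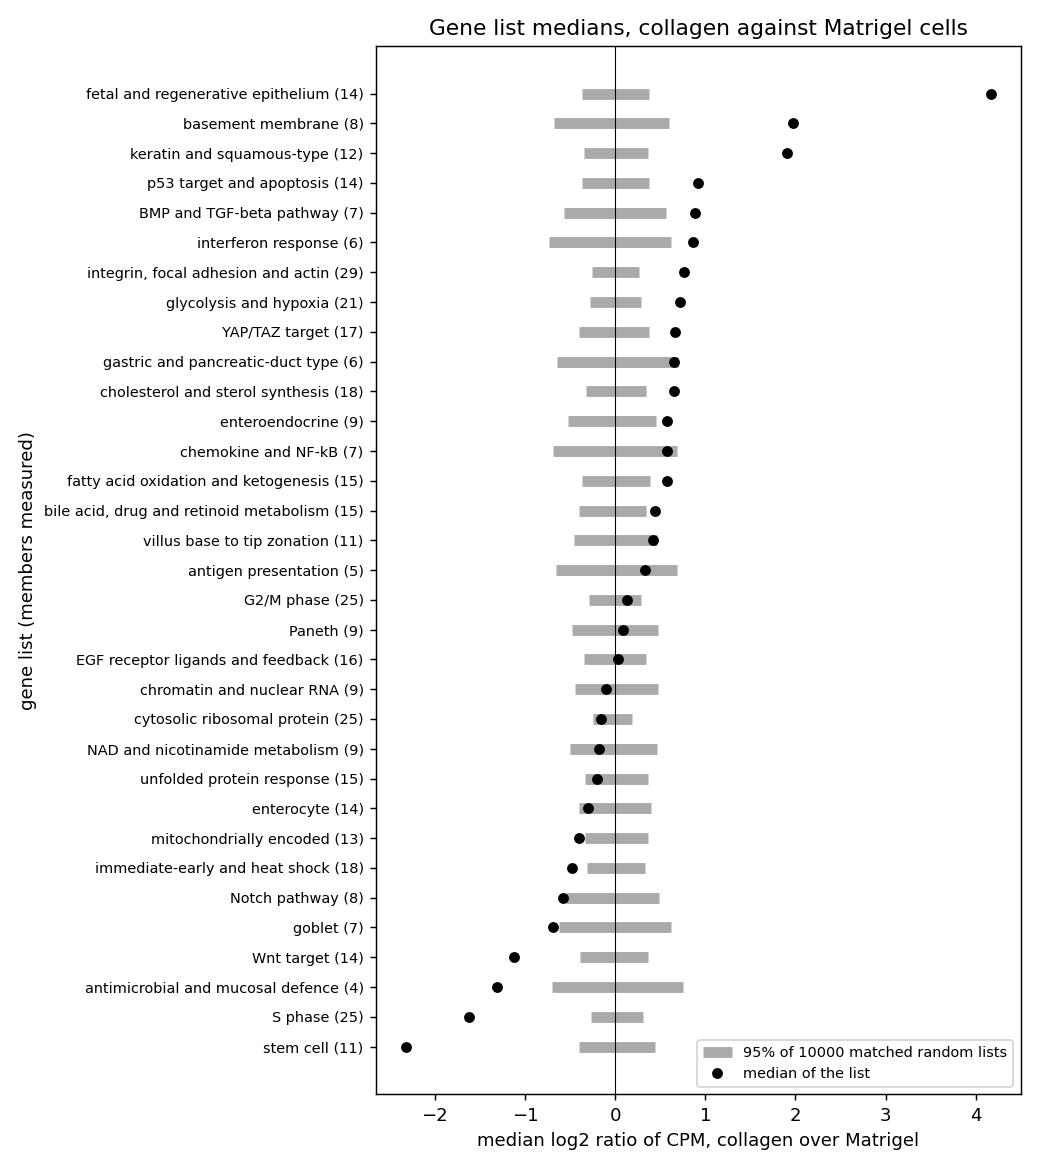
Median log2 ratio of CPM, collagen over Matrigel, for the 33 gene lists with at least 3 measured members (black points; number of members in brackets). Grey bars span 95% of 10000 random lists matched on expression. The fetal and regenerative list lies at 4.17 and the stem cell list at -2.32.

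The third question was how the kinds of intestinal cell differed between the cultures, first by markers in single cells. After each cell was thinned to 77972 counts, which left out 72 collagen and 122 Matrigel cells below that depth, Lgr5 was found in 42.8% of 264 collagen cells (36.8 to 49.01) and in 91.7% of 1477 Matrigel cells (90.2 to 93.1). Olfm4 was found in 3 collagen cells, or 1.14% (0.235 to 3.28), and in 82.3% of Matrigel cells (80.3 to 84.2). The regenerative markers went the other way, with Clu in 71.2% (65.3 to 76.6) against 13.5% (11.8 to 15.3), Anxa1 in 58.3% (52.1 to 64.3) against 13.7% (11.96 to 15.5) and Ly6a in 45.8% (39.7 to 52.1) against 3.45% (2.58 to 4.52). As background, Matrigel cells of the enterocyte-like cluster, thinned to the same depth, had a count of Lgr5 in 23.1% of 52 cells, of Anxa1 in 11.5%, of Clu in 3.85% and of Olfm4 in 3.85%, and 0 had a count of Ly6a. The low values of Clu, Ly6a and Olfm4 are absent, with smallest kept values of 10, 6 and 12 counts, so their shares here and among the background cells are shares above a threshold set per gene. The Olfm4 share of collagen cells lay below that background, and the Anxa1 share of Matrigel cells was close to it. Without thinning, at median depths of 124619 and 179044 counts per cell, the shares were 46.4% against 92.8% for Lgr5, 0.893% against 79.2% for Olfm4, 67.0% against 12.6% for Clu and 44.9% against 3.31% for Ly6a. With 2 or more counts asked of a thinned cell, Lgr5 was found in 28.4% against 87.1% and Anxa1 in 48.1% against 7.38%.

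Absorptive markers were mixed. The brush border phosphatase gene Alpi was found in 46.2% of collagen cells (40.1 to 52.4) against 22.3% of Matrigel cells (20.2 to 24.6), at 87.1 CPM (84.4 to 89.99) against 37.9 CPM (37.2 to 38.6). The fatty acid binding protein gene Fabp1 was found in 50.0% (43.8 to 56.2) against 47.9% (45.4 to 50.5), although its level was 1110 CPM against 449 CPM. Fabp1 was a leading gene of the enterocyte-like Matrigel cluster, at 9527 CPM there against 233 CPM in all other cells. Those others include every collagen cell, so Matrigel cells outside the cluster stood below 233 CPM, further from the collagen level. With 2 or more counts asked of a cell, the shares were 37.5% against 15.5% for Alpi and 32.95% against 29.5% for Fabp1. Fabp2 was lower in collagen cells at 42.5 against 236 CPM, and Clec2h was higher at 18.4 against 3.58 CPM. Rbp2 (10.6 against 49.3 CPM) and the sucrase-isomaltase gene Sis (6.02 against 26.5 CPM; log2 ratio -1.97, or -2.84 at a hashtag share of 95%) were also lower. Both were leading genes of the enterocyte-like cluster of 56 Matrigel cells. Rbp2 stood at 891 CPM there and Sis at 536 CPM, against 15.9 and 6.70 CPM in all other cells, so their differences rest largely on that cluster. The enterocyte list had 4 members at least 2-fold higher and 4 at least 2-fold lower among 14, and its median of -0.30 was inside the range of its random lists and was 0.14 with members reaching 20 CPM. Mki67 was found in 50.4% (44.2 to 56.6) against 59.5% (57.0 to 62.0), the reverse order of its levels, so no order was read from it. In the 9 enteroendocrine-like Matrigel cells at this depth, Alpi was found in 0 and Fabp1 in 4.

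The secretory markers Lyz1, Muc2 and Chga sat in few cells in both cultures, while Tff3 had a count in 239 collagen and 1332 Matrigel cells and Itln1 in 200 and 1060. Lyz1, the lysozyme gene of Paneth cells, was found in 3.79% of thinned collagen cells (1.83 to 6.86) and 5.08% of Matrigel cells (4.01 to 6.32), Muc2, the goblet cell mucin gene, in 4.55% (2.37 to 7.81) and 5.08% (4.01 to 6.32), and Chga, an enteroendocrine gene, in 2.65% (1.07 to 5.39) and 1.90% (1.26 to 2.73). The low values of Lyz1 are absent, with a smallest kept value of 30 counts. Their intervals overlapped, and the enterocyte-like cells had Muc2 in 3.85%, Chga in 1.92% and Dclk1 in 17.3%. The tuft cell gene Dclk1, at 9.47% and 10.2%, was therefore at background, and no tuft gene reached 5 CPM (list sum 8.17 against 14.5 CPM). With 2 or more counts, Dclk1 was found in 0.379% and 0.474%, Muc2 in 1.52% and 2.10% and Chga in 2.27% and 0.880%. The levels of Lyz1 and Chgb rested on few collagen cells. Lyz1 stood at 622 against 122 CPM with 11 collagen cells carrying it, and Chgb at 569 against 92.5 CPM with 4. Their log2 ratios of 2.34 and 2.61 were 1.59 and 0.98 with zeros set to the smallest value kept, and 0.97 and 1.47 at a hashtag share of 95%. Tff3 (644 against 680 CPM) differed little, Itln1 was higher in collagen (327 against 123 CPM), and Gcg was lower (0.194 CPM, 0.0812 to 0.371, against 17.4 CPM, 16.9 to 17.9). The level of Gcg rested on few cells. It was a leading gene of the enteroendocrine-like cluster of 5 collagen and 18 Matrigel cells, at 2484 CPM there against 0.180 CPM in all other cells. The enteroendocrine median was 0.58, was 1.94 with members reaching 20 CPM and turned to -0.31 when cells needed 95% of their hashtag counts from 1 hashtag. The goblet median was -0.69, with Guca2a at 3.74 against 39.3 CPM and Fcgbp at 36.6 against 78.9 CPM, and turned to 0.12 with zeros of the 49 genes set to the smallest value kept, where Guca2a was at -0.25 and Fcgbp at 0.12. At a hashtag share of 95% the log2 ratio of Guca2a was -3.74.

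**Figure D3:**
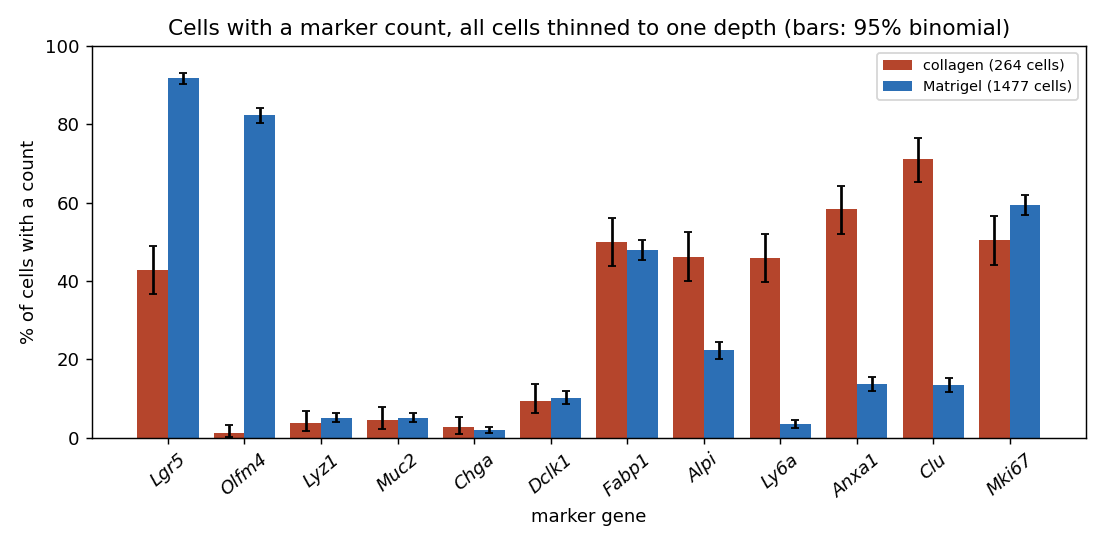
Percent of collagen cells (264) and Matrigel cells (1477) with at least 1 count of each marker gene after thinning every cell to 77972 counts, with exact 95% binomial intervals as bars. Lgr5 and Olfm4 are found in 42.8% and 1.14% of collagen cells against 91.7% and 82.3% of Matrigel cells, and Clu, Anxa1 and Ly6a are found more often in collagen cells. For Clu, Ly6a, Olfm4 and Lyz1 the deposited table lacks low values, so their bars are shares above a threshold set per gene.

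Clustering gave 16 clusters, in which collagen and Matrigel cells seldom met. Of the 336 collagen cells, 305 (90.8%, 87.2 to 93.6) lay in clusters made mostly of collagen cells, with 3 of 1599 Matrigel cells (0.188%, 0.0387 to 0.547). When genes differing over 2-fold between the cultures were kept out of the clustering, 276 collagen cells (82.1%, 77.6 to 86.1) and 3 Matrigel cells still lay in such clusters. With all variable genes, 56 Matrigel cells (3.50%, 2.66 to 4.52) were enterocyte-like, 61 (3.81%, 2.93 to 4.87) goblet or Paneth-like and 18 (1.13%, 0.668 to 1.77) enteroendocrine-like. Without the genes that differed, the enterocyte-like class held 0 of 336 collagen cells (upper limit 1.09%) and 49 of 1599 Matrigel cells (3.06%, 2.28 to 4.03). Most collagen cells lay in clusters of their own, so this limit does not cover enterocyte-like cells inside those clusters. The goblet or Paneth-like class held 4 collagen cells (1.19%, 0.325 to 3.02) and 46 Matrigel cells (2.88%, 2.11 to 3.82), and the enteroendocrine-like class 5 (1.49%, 0.485 to 3.44) and 17 (1.06%, 0.621 to 1.70). Under 4 other settings no cluster of Matrigel cells was enterocyte-like by its leading genes. With 1 suspension per culture, a cluster made mostly of collagen cells may be the culture and not a cell type. The largest number of cells that a named class held in both cultures was 5, so levels within a class were not compared.

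Genes of other cell types were low among the tagged cells of both cultures. The hashtag bound through EpCAM, so cells without EpCAM would carry no culture name, and these levels do not measure how many such cells the cultures held. Epcam, the epithelial gene used for tagging, stood at 1458 CPM (1447 to 1470) against 1076 CPM (1072 to 1079). The summed level of the fibroblast list was 18.998 against 6.11 CPM, mostly from Vim (17.5 against 4.64 CPM, found in 7 and 48 cells), whose log2 ratio of 1.72 was 0.51 at a hashtag share of 95%. Vim was among the leading genes of the enteroendocrine-like cluster, at 1008 CPM there against 0.230 CPM in all other cells. The immune list summed to 2.15 against 2.08 CPM, the endothelial list to 2.40 against 2.62 CPM and the muscle, mesothelial and neural list to 8.92 against 11.8 CPM.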

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

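Each of these values is a signal in data outside the main comparisons, and of them only cells named as doublets enter any alternative, those set by hashtag share. The hashtag table also lists 9 hashtags that the labels give to no culture, with 67117 counts together, or 0.0929% of all hashtag counts. Outside the expression table, 13080 barcodes had at least 1000 counts of the collagen and Matrigel hashtags, and 5738 of them had at least 80% from the collagen hashtag and 6879 at least 80% from the Matrigel hashtag. The collagen share among those barcodes was 43.9%, against 17.2% among the 1951 cells named for a culture, and 8.19% of all collagen hashtag counts and 17.0% of all Matrigel hashtag counts lay in cells of the expression table. The authors named 139 cells as doublets, with a median of 159671 counts per cell, between the medians of collagen and Matrigel cells. In the 137 that passed the filter, Msln stood at 29.5 CPM, Ly6a at 48.6 CPM, S100a6 at 1269 CPM and Axin2 at 139 CPM, each between its levels in collagen and Matrigel cells, and Olfm4 stood at 1673 CPM, above both. No explanation was tested for these values.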

How the results depend on the processing

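The zeros set to the smallest kept value and the removal of the cluster of highest mitochondrial share were chosen after seeing the data; the other alternatives were fixed before. Of 33 list medians, 24 kept their sign under every alternative run, among them the stem cell list (-2.43 to -2.04), the S phase list (-1.77 to -1.39), the fetal and regenerative list (2.25 to 4.38) and the G2/M list (0.05 to 0.30). Of 492 alternative values of list medians, 456 moved by under 0.25 and 36 further, and 13 values, in 9 lists, had the other sign. Of 1924 alternative ratios of the 148 named genes, 1833 moved by under 0.6 and 91 further, and 7 values, in 5 genes, had the other sign. Among the 91, 32 came with a pseudocount of 5 CPM and 12 with one of 0.1 CPM, so the size of a ratio depends on the pseudocount where a level is low. Of 80 class shares 74 and of 78 marker shares 52 stayed inside their main interval. The 80 leave out the regenerative class. Its collagen share of 47.3% (41.9 to 52.8) was 83.3% without the Scrublet call and 93.6% with 1000 genes and 15% mitochondrial counts. With 2 or more counts asked of a cell, 16 marker shares fell below their main interval, such as Lgr5 in collagen cells at 28.4%, Muc2 at 1.52% and Dclk1 at 0.379%. Without thinning 10 moved, such as Dclk1 at 15.2% in collagen and 20.95% in Matrigel cells. Of the 12 genes named in each direction, 10 higher and 7 lower in collagen were also named at a minimum of 20 CPM, and 6 and 6 at 200 CPM.

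With members reaching 20 CPM, the median was -0.83 for Wnt targets, 0.14 for enterocyte, 1.94 for enteroendocrine, 0.27 for YAP/TAZ targets, 0.98 for chemokine, 1.25 for p53 targets, 0.42 for EGF receptor ligands, 0.93 for villus zonation and 0.22 for gastric genes. With every member that had a count, it was -0.76 for Wnt targets, -0.38 for goblet, 2.25 for fetal and regenerative, 1.14 for keratin, 1.04 for basement membrane, 0.067 for interferon, -0.27 for antimicrobial, -0.11 for chemokine, -0.064 for bile acid and drug, -0.030 for BMP and TGF-beta, -0.071 for villus zonation and 0.19 for gastric genes. These alternatives change which members count. A pseudocount of 5 CPM gave 3.44 for fetal and regenerative and 1.07 for basement membrane genes. A hashtag share of 95% gave -1.26 for goblet and -0.31 for enteroendocrine genes, and one of 60%, which includes cells named as doublets, gave -2.04 for stem cell genes. Thinned cells gave -0.24 for goblet and 0.96 for enteroendocrine genes. Leaving mitochondrial and ribosomal genes out of the total, which put the median of all genes at -0.10, gave -1.18 for goblet, 3.23 for fetal and regenerative, 0.13 for chemokine, 0.63 for BMP and TGF-beta and 0.039 for villus zonation genes. Zeros set to the smallest kept value gave 0.12 for goblet, 0.38 for Paneth and 2.88 for fetal and regenerative genes, and 0.12 for Fcgbp and 0.38 for Ang4. The enterocyte-like share of Matrigel cells was 0 with 15 principal components, with 1000 genes and 15% mitochondrial counts, and at hashtag shares of 95% and 60%. Without genes differing over 2-fold, 2.88% of Matrigel cells were goblet or Paneth-like and 82.1% of collagen cells lay in clusters mostly of collagen cells. Where the set of members did not change, the cause was not tested. No paired analysis was possible because each culture was 1 suspension. Weighting by class and levels within a class were not run, as no class had enough cells in both cultures. Depth limits detection to 0.0705 CPM in collagen and 0.0105 CPM in Matrigel cells, the value of 3 counts.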

Other observations

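Tests of Mt1 against the thresholded Mt2, of the G2/M list and its lowest member, of Edn1 and of the 76 Matrigel cells with few immediate-early counts were chosen after their results were seen; the other tests were set before.

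In the antimicrobial list, 2 of 4 measured genes were at least 2-fold lower in collagen cells and the others lay within 2-fold. Pigr, the receptor that carries IgA across epithelium, stood at 329 CPM in collagen cells against 1069 CPM in Matrigel cells, and Dmbt1 at 48.9 against 177 CPM, with a median log2 ratio of -1.31, or -0.27 with every member that had a count. Reg1, one of the 49 genes without low values, was found in 1 collagen and 8 Matrigel cells, and its log2 ratio of -0.18 was 0.46 with zeros set to the smallest value kept. Chemokine genes went both ways. Cxcl16 was higher in collagen cells (92.9 against 7.93 CPM) and Ccl25, the small intestinal lymphocyte attractant, lower (34.5 against 231 CPM), and the list median of 0.58 over 7 members was -0.11 with every member that had a count and 0.13 without mitochondrial and ribosomal genes in the total. The Notch list had a median of -0.58, with Dll1 at 2.67 against 10.4 CPM and Nrarp at 7.54 against 17.4 CPM. The interferon list had a median of 0.87 over 6 members (Stat2 13.8 against 4.54 CPM, Ifi27l2b 255 against 114 CPM), which was 0.067 with every member that had a count. Antigen presentation genes had a median of 0.33, with H2-D1 at 298 against 148 CPM.

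Among EGF receptor ligands, Areg (175 against 44.1 CPM) and Btc (69.4 against 24.6 CPM) were higher in collagen cells, and the feedback gene Spry1 was lower (3.57 against 11.2 CPM), with a list median of 0.03, or 0.42 with members reaching 20 CPM. In the gastric and pancreatic-duct list, Anxa10 (74.0 against 5.67 CPM) and Onecut2 (190 against 86.5 CPM) were higher and Muc4 (3.00 against 21.4 CPM; log2 ratio -2.49, or -1.83 at a hashtag share of 60%) lower, with a median of 0.65, or 0.19 with every member that had a count. Villus zonation genes had a median of 0.42, with Apob at 103 against 22.7 CPM and Creb3l3 at 20.5 against 2.85 CPM, and the median was -0.071 with every member that had a count. Nicotinamide was added to the collagen medium alone, and the NAD list had a median of -0.18, inside its random range, with Parp1 at 33.3 against 87.5 CPM. The chromatin list had a median of -0.10, with Hmga2 at 14.1 against 61.1 CPM. Paneth genes had a median of 0.09, unfolded protein response genes -0.21 (Ddit3 26.9 against 10.4 CPM) and ribosomal protein genes -0.16.

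Metallothioneins Mt1 and Mt2 were lower in collagen cells, while the zinc importer gene Slc39a4 was higher (253 against 17.9 CPM, log2 ratio 3.75). A threshold on Mt2 cannot account for the lower Mt1, which has none and had a log2 ratio of -3.54. No single Matrigel cluster carried the Mt1 difference, since the lowest Mt1 level among 11 Matrigel clusters of at least 30 cells was 6.55 times the collagen level. Collagen and Matrigel cells seldom shared a cluster, so this cannot decide whether cell state is the cause. A candidate explanation is a lower supply of usable zinc to collagen cells, for which the zinc-induced exporter gene Slc30a1 should be lower and the zinc-repressed importer gene Slc39a10 higher. Slc30a1 had a log2 ratio of -1.54 (4.35 against 14.6 CPM) and Slc39a10 one of 1.62 (31.4 against 9.55 CPM), as this hypothesis requires, while Mtf1, the gene of the zinc-sensing factor, stood at 12.8 against 11.7 CPM and Slc30a10 at 5.02 against 4.68 CPM. Zinc was not measured, and matrix, albumin in the medium and cell state differed together.

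Ccn1 and Edn1 were lower in collagen cells while most other YAP and TAZ targets that differed were higher. Both are also induced within minutes of stress, so a response of Matrigel cells to dissociation might account for this. In the 533 Matrigel cells with the lowest share of 13 immediate-early genes, Ccn1 was still 7.96 times the collagen level, but they had a median of 1292 CPM of those genes against 924 CPM in collagen cells. In the 76 Matrigel cells at or below the collagen median, Ccn1 stood at 77.8 CPM, 4.57 times the collagen level. The summed share of these genes therefore did not account for the whole Ccn1 difference. Edn1 was 2.89 times the collagen level in the 533 cells and 2.60 times in the 76, which leaves Edn1 open. The 76 cells were chosen by the sum and not by each gene. Over all cells, Junb, Jund, Ier3 and Fosl1 were higher in collagen cells and the other immediate-early genes lower. Matrigel cells with an equal sum may thus still hold more Fos or Jun, so a response to dissociation is not excluded for Ccn1. A single Matrigel cluster was not the whole source, since the lowest level in any of 11 clusters was 6.10 times the collagen level for Ccn1 and 2.11 times for Edn1, although Edn1 was unevenly spread and led a cluster of Matrigel cells at 550 CPM against 131 CPM in all other cells.

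S phase genes were lower in collagen cells and G2/M genes were not. Fewer dividing collagen cells, or dilution by cells that do not divide, would as the whole cause lower both lists alike, but the G2/M median was 0.13 and its lowest member, Cdk1, was at -0.80, against an S phase median of -1.62. Thinning, which gave an S phase median of -1.67, could not test depth, since ratios of scaled sums hardly move with it. Cells with a Mki67 or Top2a count made up 59.8% of thinned collagen cells and 74.5% of thinned Matrigel cells. Fewer dividing cells as a part of the cause are therefore not excluded. Cells with such a count had an S phase median of -1.30, which decides nothing, because Mki67 and Top2a are on the G2/M list and Mki67 was found in 21.2% of enterocyte-like cells. A different balance of phases among dividing collagen cells may be involved and was not tested.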
